A study of Caenorhabditis elegans with 18 samples.

How the data were processed

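RNA of whole L1 larvae was sequenced in 18 libraries from 3 genotypes (N2, raga-1 and rsks-1), starved or fed, with 3 libraries per group. Per the labels, total RNA was extracted with TRIzol after freeze-thaw cycles, purified on a column and treated with DNase I. The deposited tables hold expected counts per gene and per isoform, not scaled to depth. The submitters' processing notes name STAR in 2-pass mode, RSEM and DESeq2, with versions not given, and name the genome WBcel269, a build name that could not be matched to the reference used here (WBcel235). Library preparation, read length and strandedness are not given in the sources used here.

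The gene table held 46904 gene identifiers, of which 44017 had a name in the reference and 2887 had none, the latter with 1.954% of counts. Of the isoforms 61351 of 61451 were matched to a gene by sequence name, and for 46799 of 46811 genes in both tables the isoform sum lay within 1 count of the gene value in every library. Of the gene values 0.962% were not whole, and values were rounded before testing. RSEM divides reads shared by paralogues between them, which affects genes with close copies. Library totals ranged from 9929323 to 18539402 counts. Protein-coding genes took 94.17 to 96.11% of counts and the 10 most abundant genes 7.59 to 9.79%. Over 18 pairs of replicates, with at least 20 counts in the pair, the mean chi-square of the difference between replicates was 2.12 to 5.99, where counting error alone gives 1.

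Genes were kept by filterByExpr of edgeR 4.0.16 in R 4.3.3 (minimum count 10), scaled by TMM and tested with the robust quasi-likelihood method in a model with one mean per group, fitted on all libraries with 12 residual degrees of freedom. The common biological coefficient of variation was 0.042. The 10 comparisons were feeding in each genotype, the differences between feeding responses, and each mutant against N2 in each state. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The standard error of a log2 change was taken as its size divided by the square root of F. As F comes from a likelihood ratio, this can be too small for large changes with few counts in a group. A group with 0 counts was compared at a floor of 3 counts over the group, and 1 to 3 counts as a ratio with a 95% counting interval.

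Of 42 gene lists written before the data were examined, those with at least 5 tested genes were tested with camera of limma 3.58.1 on voom values (correlation 0.01), adjusted by Benjamini-Hochberg over the lists, with an estimated correlation and the fry test beside it. With genes at few counts set to their bound, 4 of 287 list medians moved by over 0.05, the largest move being 0.096. Named genes were chosen by a rule written before the data were examined. For feeding and for differences between responses these are genes with a letters-hyphen-number name, adjusted p below 0.05 and a mean of at least 10 CPM in a compared group, up to 8 with the highest and up to 8 with the lowest log2 change, or a subset from the top of each ranking. For feeding the CPM of fed and starved libraries also could not overlap, which chance gives for 10% of genes with 3 against 3 libraries. For mutant against N2 up to 5 each way were taken, and from each list up to 4 members with the largest changes past the threshold, or up to 2 not past it where none was. The target genes raga-1 and rsks-1 are given in every group. Response size is the slope of a mutant's log2 changes on those of N2, over genes at least 2-fold changed on feeding in the other mutant.

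The methods were tested on simulated data with 50 changed genes at each of 1.25, 1.5, 2 and 4-fold. For feeding in N2 21, 34, 45 and 48 were recovered, with 8 unchanged genes called, for the difference between raga-1 and N2 responses 16, 28, 38 and 46, with 4, and for raga-1 minus N2 in fed larvae 23, 36, 40 and 49, with 6. All other genes were unchanged in these simulated data, whereas 10399 of 14073 genes were called on feeding in N2. Recovery and false calls may differ where most genes change. Simulated response sizes of 0.5 and 0.8 came back as 0.472 and 0.766. The alternatives were relative log expression factors, the DESeq2 1.42.0 Wald test, no filter, a replicate block, only the libraries compared, sums of isoform counts, each library left out, other gene selections for response size, and, chosen after seeing the data, library totals alone, every library thinned to the lowest total, and gene lists without each library. Tables were handled with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and figures drawn with matplotlib 3.10.9. No library was left out, and the isoform table was used only for the checks and the alternative above.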

Results

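RNA from whole first-stage (L1) Caenorhabditis elegans larvae was sequenced in 18 libraries, 3 for each of 6 groups. The larvae were wild type (N2), raga-1(ok386) mutants or rsks-1(ok1255) mutants. The gene raga-1 encodes the RagA GTPase, which relays amino acid supply to the kinase complex TORC1, and rsks-1 encodes the ribosomal protein S6 kinase, a TORC1 substrate. Per the labels, eggs were isolated by bleaching from worms grown at 20 °C and kept for 24 h in M9 buffer without food. The hatched larvae were collected starved or after 4 h of feeding on OP50 bacteria. Library totals were 10261804 to 13012442 counts in starved and 9929323 to 11246940 in fed N2. They were 13146918 to 18539402 in starved and 13446155 to 14508882 in fed raga-1, and 11313180 to 15867607 in starved and 10840870 to 16714185 in fed rsks-1. Of the 46904 genes in the table, 14073 had enough counts to be tested. Noncoding RNA genes took 0.788 ± 0.0271% of counts in starved and 0.202 ± 0.0140% in fed N2 (SD, n = 3 libraries). They took 0.561 ± 0.0167% and 0.330 ± 0.0147% in raga-1, and 0.737 ± 0.0267% and 0.235 ± 0.00577% in rsks-1. The labels do not say whether the replicates came from separate cultures, so the p-values may measure technical spread.

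**Figure D1:**
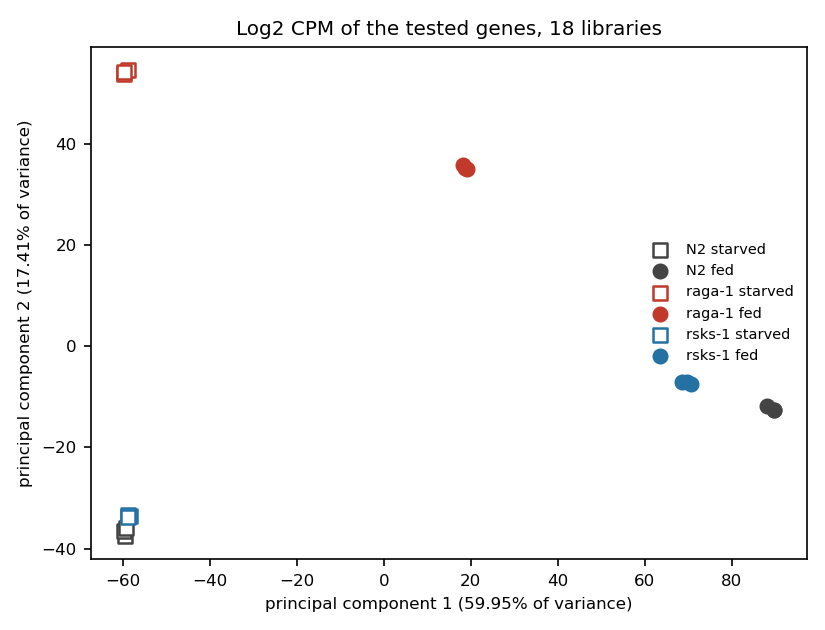
Scores of the 18 libraries on principal components 1 (59.95% of variance) and 2 (17.41%) of log2 CPM of the tested genes, with genotype as colour, fed libraries as filled circles and starved libraries as open squares. Fed N2 libraries lay at 88.2 to 89.8 on the horizontal axis, fed rsks-1 libraries at 68.6 to 70.7 and fed raga-1 libraries at 18.3 to 19.2.

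The gene raga-1 (WBGene00006414, chromosome II, 11301359 to 11302776, plus strand, build WBcel235) was at 50.1 ± 1.00 CPM (TMM-scaled counts relative to the library total, SD, n = 3 libraries per group here and below) in starved N2 and 64.1 ± 1.44 CPM in fed N2. It rose on feeding in N2 (log2 change 0.36, SE 0.07, adjusted p = 3.03e-06, edgeR QL, Benjamini-Hochberg). It was at 46.9 ± 3.61 and 47.4 ± 2.43 CPM in starved and fed rsks-1 mutants, where its response to food was smaller than in N2 (difference in log2 change -0.34, SE 0.10). All 6 raga-1 libraries held 0 counts of raga-1, at least 858-fold lower than N2 in starved and at least 955-fold lower in fed larvae against a floor of 3 counts over the group. The gene rsks-1 (WBGene00012929, chromosome III, 11245120 to 11252281, plus strand) was at 186 ± 9.39 and 171 ± 9.24 CPM in starved and fed N2 and at 177 ± 4.74 and 165 ± 6.64 CPM in raga-1 mutants. In rsks-1 mutants it was at 37.6 ± 3.69 CPM starved and 24.8 ± 2.65 CPM fed. Both levels were lower than in N2 (log2 change -2.31, SE 0.05 starved, log2 change -2.80, SE 0.06 fed). It fell on feeding in N2 (log2 change -0.12, SE 0.05) and by more in rsks-1 mutants (log2 change -0.61, SE 0.07, difference in log2 change -0.49, SE 0.08). Under library totals alone the changes of raga-1 on feeding in N2 (log2 change 0.05) and its difference between rsks-1 and N2 (-0.23) did not pass the threshold. The fall of rsks-1 in N2 did not pass it without starved N2 replicate 1 (-0.09) or fed N2 replicate 2 (-0.08). Ratios against groups with few counts carry intervals and floors that cover counting error only.

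The first comparison asks which transcripts change when arrested N2 larvae are fed. The gene acs-2, which encodes an acyl-CoA synthetase of mitochondrial fatty acid oxidation, went from 1907 ± 30.2 to 0.594 ± 0.139 CPM (log2 change -11.62, SE 0.07, adjusted p = 3.93e-142, edgeR QL, Benjamini-Hochberg). Fed N2 libraries held only 7, 4 and 5 counts of acs-2, so counting error exceeds this SE. The SE of other large changes against few counts, here and below, is likely too small as well. The glyoxylate cycle enzyme icl-1 went from 4322 ± 41.6 to 32.2 ± 0.780 CPM (log2 change -7.07, SE 0.04). The alcohol dehydrogenase adh-1 went from 8220.0 ± 142 to 9.94 ± 1.26 CPM and the flavin-containing monooxygenase fmo-2 from 878 ± 7.89 to 1.49 ± 0.404 CPM (log2 changes -9.69 and -9.19, SE 0.05 and 0.08). The lysosomal lipase lipl-3 and poml-4 fell (log2 changes -8.24 and -7.09, SE 0.18 and 0.31). The gene mltn-1 had 0 counts in fed larvae (at least 163-fold lower) and the cytochrome P450 cyp-37B1 had 2 (ratio 594, 95% counting interval 164 to 4910.0 lower in fed larvae). In the other direction irg-4 and irg-5, named as infection response genes, rose (log2 changes 8.03 and 5.42, SE 0.07 and 0.23), with irg-4 going from 2.38 ± 0.487 to 618 ± 1.80 CPM. The cytochrome P450 genes cyp-35D1 and cyp-35A5, the cuticle collagen col-149 and the saposin-like spp-17 rose (log2 changes 7.83, 6.40, 6.14 and 5.48, SE 0.27, 0.21, 0.20 and 0.16). The astacin protease nas-3 (ratio 523, 95% counting interval 144 to 4327) and the C-type lectin clec-206 (ratio 188, 95% counting interval 63.9 to 916) were higher in fed larvae from 2 and 3 counts in starved larvae.

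Genes for making proteins rose together. Of 53 tested genes for ribosome biogenesis and RNA polymerase I, 47 rose and 5 fell (median 1.65, camera adjusted p = 2.54e-15). The nucleolar proteins fib-1, nifk-1 and nol-56 rose most (log2 changes 3.48, 3.30 and 3.09, SE 0.03, 0.05 and 0.03). Of 81 cytosolic ribosomal protein genes 73 rose and 1 fell (median 0.61, camera adjusted p = 3.84e-23, and adjusted p = 0.0779 with an estimated correlation, counts 74 and 1 adjusted over the list alone). The largest change in that list was a rise of rpl-41.1 (log2 change 1.69, SE 0.16), and the fall was of rpl-24.2, a homologue of a ribosome biogenesis factor (log2 change -1.01, SE 0.03). Mitochondrial ribosomal protein genes rose in 62 of 66 cases and fell in 3 (median 1.29, camera adjusted p = 9.62e-15). Translation factors rose in 40 of 42 cases, with 1 lower (median 1.37, camera adjusted p = 1.61e-18). The largest rise was of inf-1, an eIF4A helicase (log2 change 3.01, SE 0.03). All 20 cytosolic aminoacyl-tRNA synthetase genes rose (median 1.58, camera adjusted p = 6.87e-14). At the top were kars-1 and nars-1 (log2 changes 3.00 and 2.45, SE 0.04 and 0.05). DNA replication and cell cycle genes rose in 59 of 64 cases and none fell (median 1.64, camera adjusted p = 1.48e-14). The replication helicase subunit mcm-7 and the sliding clamp pcn-1 rose most (log2 changes 2.80 and 2.67, SE 0.08 and 0.06).

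Protein folding and degradation genes rose as well. In the list of endoplasmic reticulum (ER) chaperones and the unfolded protein response, 32 of 37 rose and 3 fell (median 1.67, camera adjusted p = 2.03e-14). The protein disulfide isomerase pdi-2 went from 218 ± 2.87 to 1647 ± 29.3 CPM (log2 change 2.92, SE 0.03). The largest change in the list was in uggt-2, lower with 1 count in fed larvae (ratio 55.0, 95% counting interval 9.58 to 2200.0). Cytosolic and mitochondrial chaperones rose in 30 of 36 cases and fell in 3 (median 1.39, camera adjusted p = 4.08e-13). The highest were hsp-1 and hsp-110 (log2 changes 3.37 and 3.01, SE 0.03 and 0.04). Proteasome subunit genes rose in 32 of 33 cases and fell in 1 (median 1.57, camera adjusted p = 1.17e-16). At its top were pas-5 and pas-4 (log2 changes 2.22 and 2.22, SE 0.06 and 0.06). Subunits of the V-ATPase, the proton pump of lysosomes, rose in 18 of 22 cases and fell in 1 (median 0.61, camera adjusted p = 4.07e-07, counts 19 and 1 adjusted over the list alone). Genes of the propionate, methionine and one-carbon list rose in 22 of 31 cases and fell in 6 (median 0.78, camera adjusted p = 0.000203, counts 23 and 6 adjusted over the list alone). Its highest were acdh-1 and the S-adenosylmethionine synthetase sams-1 (log2 changes 2.65 and 2.11, SE 0.05 and 0.03).

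Of 27 autophagy genes, 21 fell and 2 rose (median -1.03, camera adjusted p = 4.27e-07). The Atg8 homologues lgg-2 and lgg-1 fell most, the latter from 653 ± 14.7 to 90.2 ± 1.01 CPM (log2 changes -3.67 and -2.86, SE 0.05 and 0.04). In the list of stress and dormancy genes activated by the transcription factor DAF-16, 21 of 28 fell and 4 rose (median -1.28, camera adjusted p = 2.16e-05). After icl-1 came the noncoding RNA tts-1 (log2 change -7.01, SE 0.10). Lysosomal lipases and membrane proteins fell in 15 of 23 cases and rose in 5 (median -0.80, camera adjusted p = 0.00727). Fatty acid oxidation genes fell in 23 and rose in 14 of 42 (median -0.51, camera adjusted p = 0.0478, and adjusted p = 0.0658 under library totals alone). Genes of the glyoxylate cycle, gluconeogenesis and trehalose fell in 13 and rose in 4 of 18 (median -0.52, camera adjusted p = 0.000574). The insulin receptor daf-2 and the kinase akt-1 led the list of TORC1 and nutrient-sensing components (log2 changes -1.86 and -1.41, SE 0.05 and 0.06). In it 10 rose and 11 fell (median -0.04, camera adjusted p = 0.402). Neuropeptide genes fell in 85 of 95 cases and rose in 4 (median -1.09, camera adjusted p = 3.57e-17). The list was taken by flp and nlp gene names, and whether each member is expressed in neurons was not tested. Genes that fell included nlp-32 (at least 4.29-fold lower in fed larvae) and nlp-2 (log2 change -3.31, SE 0.16). Neuron markers fell in 21 of 24 cases (median -0.40, camera adjusted p = 4.75e-06).

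In all, 10399 of 14073 genes changed on feeding in N2, 5134 higher and 5265 lower, and of these 2294 were at least 2-fold higher and 2656 at least 2-fold lower. Camera called 22 of the 41 lists, 20 with an estimated correlation. Counts adjusted over the list alone are given where they differ from those adjusted over all genes tested. Scaling by library totals alone moved the median of all genes from -0.07 to -0.36 and the share of calls that were higher from 49.4% to 35.6%.

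The next comparisons ask how much of the feeding response remains without raga-1. In raga-1 mutants acs-2 fell from 253 ± 3.11 to 1.03 ± 0.158 CPM (log2 change -7.92, SE 0.07, adjusted p = 4.96e-123, edgeR QL, Benjamini-Hochberg). The level of icl-1 went from 1218 ± 19.4 to 23.3 ± 2.67 CPM and adh-1 from 1600.0 ± 28.4 to 38.01 ± 0.529 CPM (log2 changes -5.71 and -5.39, SE 0.04 and 0.04). The lectin clec-9 fell to 3 counts (ratio 148, 95% counting interval 50.3 to 719). The genes idpc-4, the cytochrome P450 cyp-34A10, fmo-2 and abu-10 fell (log2 changes -6.32, -5.82, -5.37 and -5.36, SE 0.29, 0.22, 0.10 and 0.34). The genes cyp-35D1, irg-5, irg-4 and the metallothionein mtl-2 rose (log2 changes 7.09, 4.21, 4.07 and 3.55, SE 0.20, 0.15, 0.05 and 0.18). Next were spp-17 and the acid sphingomyelinase asm-3 (log2 changes 3.41 and 3.35, SE 0.15 and 0.12). Among the lists, ribosome biogenesis genes rose in 47 and fell in 3 of 53 cases (median 1.02, camera adjusted p = 1.73e-22). At its top were nifk-1 and fib-1 (log2 changes 1.79 and 1.58, SE 0.05 and 0.03), with fib-1 reaching 1246 ± 29.1 CPM from 416 ± 7.04 CPM. Aminoacyl-tRNA synthetase genes rose in all 20 cases (median 0.78, camera adjusted p = 2.14e-15). Proteasome genes rose in 32 and none fell (median 0.52, camera adjusted p = 8.21e-12). ER chaperones rose in 20 and fell in 8 of 37 cases (median 0.16 but mean -0.003, camera adjusted p = 0.0396, and adjusted p = 0.112 with an estimated correlation, and adjusted p = 0.206 under library totals alone, counts 20 and 9 adjusted over the list alone). The largest changes in that list were falls of uggt-2 and the BiP chaperone hsp-4 (log2 changes -2.78 and -1.73, SE 0.34 and 0.05). Autophagy genes fell in 21 and rose in 2 cases (median -0.44, camera adjusted p = 9.22e-07). The gene lgg-2 fell to 138 ± 1.70 CPM from 347 ± 6.27 CPM (log2 change -1.33, SE 0.04). Cuticle collagen genes fell in 63 and rose in 14 of 106 cases (median -0.77, camera adjusted p = 0.000201, and adjusted p = 0.0631 with an estimated correlation, counts 14 and 64 adjusted over the list alone). Fatty acid oxidation genes fell in 32 and rose in 7 of 42 (median -0.95, camera adjusted p = 9.87e-11).

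Feeding changed 8775 genes in raga-1 mutants, 4143 higher and 4632 lower, with 606 at least 2-fold higher and 1549 at least 2-fold lower. Higher and lower were 4434 and 4194 with only the libraries compared, which turns the majority, and 3371 and 5570 under library totals alone. Camera called 24 of the 41 lists, 19 with an estimated correlation. Of the genes at least 2-fold higher on feeding in N2, 532 were so in raga-1, against 98.8 for independent lists. Of those at least 2-fold lower 1038 were so against 292.3. These comparisons share no library. Over 4047 genes at least 2-fold changed on feeding in rsks-1 mutants, a set chosen without N2 or raga-1 libraries, the log2 response of raga-1 regressed on that of N2 had a slope of 0.420, with a median ratio of 0.471.

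**Figure D2:**
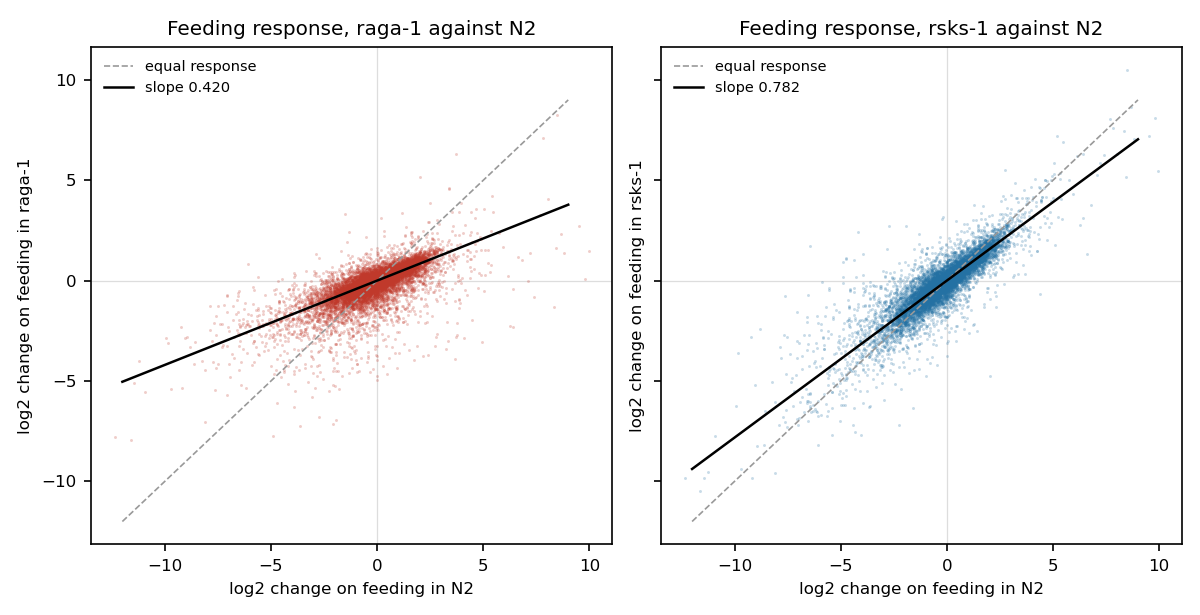
Log2 change on feeding in raga-1 (left) and rsks-1 mutants (right) against log2 change on feeding in N2, one point per tested gene, with a dashed line for an equal response and a solid line with the slope of the response. The slopes were 0.420 in raga-1, over 4047 genes at least 2-fold changed in rsks-1, and 0.782 in rsks-1, over 2155 genes at least 2-fold changed in raga-1. They were not fitted to all points drawn, and the gene sets differ between the panels.

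Tested directly, the raga-1 response differed from that of N2 in a range of genes. The P450 gene cyp-35A5 rose from 0.305 ± 0.211 to 27.75 ± 0.581 CPM in N2. In raga-1, where its starved level was already high, it went from 32.6 ± 1.01 to 24.3 ± 0.170 CPM (difference in log2 change -6.83, SE 0.24), with adjusted p = 9.84e-55 (edgeR QL, Benjamini-Hochberg). The leucine-rich repeat protein sym-1 went from 0.813 ± 0.251 to 11.3 ± 1.23 CPM in N2 and from 6.003 ± 0.562 to 0.928 ± 0.411 CPM in raga-1 (difference in log2 change -6.46, SE 0.33). The differences for clec-206 and nas-3 were also negative (differences in log2 change -8.21 and -7.40, SE 0.38 and 1.11). Those for cyp-37B1, the ammonium transporter amt-1 and mltn-1 were positive (differences in log2 change 6.17, 5.46 and 5.37, SE 0.52, 1.31 and 1.80). These last 5 genes had at most 3 counts in a group of N2, amt-1 and mltn-1 with 0 in fed N2, so their fitted sizes depend on the prior count. The difference for mltn-1 did not pass the threshold without fed raga-1 replicate 1 (4.14). ER chaperones had a negative difference in 34 of 37 cases and a positive one in 2 (median -1.46, camera adjusted p = 1.03e-27, counts 2 and 35 adjusted over the list alone). Of these hsp-4 and pdi-2 differed most (differences in log2 change -3.17 and -2.87, SE 0.09 and 0.04), and pdi-2 went from 706 ± 18.9 to 731 ± 22.8 CPM in raga-1. The difference was negative for 32 of 33 proteasome genes (median -1.09, camera adjusted p = 5.14e-20) and 19 of 20 aminoacyl-tRNA synthetase genes, with 1 positive (median -0.86, camera adjusted p = 8.53e-13). It was negative for 53 and positive for 1 of 64 DNA replication genes (median -0.83, camera adjusted p = 3.50e-10, counts 1 and 54 adjusted over the list alone), and negative for 42 and positive for 7 of 53 ribosome biogenesis genes (median -0.68, camera adjusted p = 7.36e-10). Among the latter the largest difference was in fib-1 (difference in log2 change -1.89, SE 0.04). Positive differences prevailed among autophagy genes, with 17 of 27 higher and 2 lower (median 0.61, camera adjusted p = 1.75e-07), as for lgg-2 (difference in log2 change 2.33, SE 0.06). The same held for DAF-16 genes, with 15 of 28 higher and 7 lower (median 0.78, camera adjusted p = 0.00286). It held for neuropeptide genes too, with 74 of 95 higher and 3 lower (median 0.74, camera adjusted p = 1.46e-19, counts 76 and 3 adjusted over the list alone), and for neuron markers, with 12 of 24 higher and 0 lower (median 0.18, camera adjusted p = 7.48e-05). Cytosolic ribosomal proteins were lower in 56 of 81 cases and higher in 1 (median -0.16, camera adjusted p = 1.60e-07, and adjusted p = 0.325 with an estimated correlation, with the median turned to 0.04 and adjusted p = 0.779 under library totals alone). Fatty acid oxidation genes had 25 negative and 9 positive differences of 42 (median -0.58, camera adjusted p = 0.00185). Cuticle collagens had 43 negative and 16 positive of 106 (median -0.73, camera adjusted p = 0.00197, and adjusted p = 0.111 with an estimated correlation, counts 17 and 45 adjusted over the list alone). Both lists had a lower median on feeding in raga-1 than in N2, so their fall was not smaller in raga-1.

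The response differed between raga-1 and N2 for 7110 genes, 3063 with a positive and 4047 with a negative difference, and 3675 and 3371 with only the libraries compared, which turns the majority. Camera called 23 of the 41 lists, 19 with an estimated correlation. Of the 2294 genes at least 2-fold higher on feeding in N2, 2028 (88.4%) had a negative difference in this test, and of the 2656 at least 2-fold lower 1696 (63.9%) had a positive one. The opposite sign was called for 14 and 44. Data simulated with equal responses gave 0.00% and 0.00%. In them no gene differed in response, so hardly any call could arise. These values do not measure what the choice of genes on N2 adds. The N2 libraries that choose these genes also enter the difference, which favours a smaller response in the mutant. Under library totals alone the share of these differences that were positive went from 43.1% to 61.7%, with the median of all genes at 0.16 in place of -0.03.

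In rsks-1 mutants feeding lowered acs-2 from 1098 ± 10.8 to 0.724 ± 0.359 CPM (log2 change -10.46, SE 0.07, adjusted p = 9.37e-140, edgeR QL, Benjamini-Hochberg). It lowered fmo-2 from 1132 ± 1.99 to 1.29 ± 0.419 CPM and adh-1 from 7823 ± 37.2 to 11.5 ± 1.15 CPM (log2 changes -9.81 and -9.39, SE 0.07 and 0.04). The gene mltn-1 fell to 3 counts (ratio 239, 95% counting interval 81.4 to 1161). The genes tts-1 and icl-1 fell (log2 changes -7.17 and -6.88, SE 0.10 and 0.04). The P450 gene cyp-35D1 and the myo-inositol transporter hmit-1.1 rose (log2 changes 7.62 and 7.18, SE 0.25 and 0.28), as did nas-3, spp-17 and irg-4 (log2 changes 7.04, 6.91 and 6.32, SE 0.25, 0.17 and 0.06). The gene hmit-1.1 has a close paralogue, hmit-1.2, with which reads may be shared. Ribosome biogenesis genes rose in 49 and fell in 2 of 53 cases (median 1.71, camera adjusted p = 1.78e-20, counts 50 and 2 adjusted over the list alone). At its top were nifk-1 and fib-1 (log2 changes 3.11 and 2.95, SE 0.05 and 0.03), with fib-1 going from 189.9 ± 2.67 to 1469 ± 49.2 CPM. Aminoacyl-tRNA synthetases rose in all 20 cases (median 1.33, camera adjusted p = 3.46e-14) and proteasome genes in 32 of 33 (median 1.11, camera adjusted p = 1.91e-14). ER chaperones rose in 30 of 37 with 4 lower (median 1.00, camera adjusted p = 1.21e-09), and DNA replication genes in 59 of 64 with none lower (median 0.99, camera adjusted p = 8.21e-13). Fatty acid synthesis, desaturation and elongation genes rose in 20 and fell in 8 of 28 cases (median 0.85, camera adjusted p = 1.66e-05). The stearoyl-CoA desaturase fat-7 and the elongase elo-2 rose most (log2 changes 4.27 and 3.06, SE 0.25 and 0.04). Autophagy genes fell in 21 and rose in 2 of 27 cases (median -1.24, camera adjusted p = 1.27e-08), with lgg-2 at 355 ± 3.38 and 28.8 ± 0.939 CPM (log2 change -3.62, SE 0.04). Neuropeptide genes fell in 75 and rose in 6 of 95 cases (median -0.48, camera adjusted p = 2.96e-11, and adjusted p = 0.0540 with an estimated correlation).

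Feeding changed 9968 genes in rsks-1 mutants, 5021 higher and 4947 lower, with 1823 at least 2-fold higher and 2224 at least 2-fold lower. Camera called 27 of the 41 lists, 22 with an estimated correlation. At least 2-fold higher in both N2 and rsks-1 were 1583 genes, against 297.2 for independent lists, and at least 2-fold lower in both were 1802 against 419.7. Over 2155 genes chosen on raga-1 libraries in the same way, the slope of the rsks-1 response on that of N2 was 0.782 and the median ratio 0.867. The share of calls that were higher went from 50.4% to 48.4% under relative log expression factors, 48.7% with DESeq2 and 38.9% under library totals alone, with the median of all genes at -0.21.

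Between rsks-1 and N2 the tested difference in response was positive for the lipase lipl-3 and the P450 gene cyp-37B1 (differences in log2 change 3.18 and 3.85, SE 0.42 and 0.63). The fatty acid desaturase fat-2 went from 1680.0 ± 35.7 to 706 ± 6.26 CPM in N2 and from 955 ± 9.64 to 2137 ± 20.1 CPM in rsks-1 (difference in log2 change 2.41, SE 0.04), with adjusted p = 9.15e-91 (edgeR QL, Benjamini-Hochberg). For cyp-37B1 the fitted size depends on the prior count, with 2 counts in fed N2. In the list of fatty acid synthesis, desaturation and elongation 17 of 28 differences were positive and 4 negative (median 0.32, camera adjusted p = 2.87e-17, counts 19 and 4 adjusted over the list alone). Next after fat-2 was fat-3 (difference in log2 change 2.22, SE 0.04). Negative differences were found for the collagen col-93, the saposin-like spp-4 and the glutathione S-transferase gst-24 (differences in log2 change -2.92, -2.78 and -2.62, SE 0.16, 0.44 and 0.10). They were also found for 31 of 37 ER chaperones (median -0.60, camera adjusted p = 3.64e-29, counts 1 and 33 adjusted over the list alone). At the top of that list were pdi-2 and pdi-3 (differences in log2 change -1.199 and -1.19, SE 0.04 and 0.04). The same sign held for 41 of 64 DNA replication genes (median -0.58, camera adjusted p = 4.15e-15, counts 0 and 46 adjusted over the list alone) and 31 of 33 proteasome genes (median -0.44, camera adjusted p = 9.27e-20, counts 0 and 32 adjusted over the list alone). It held for 16 of 22 V-ATPase genes, against 1 positive (median -0.32, camera adjusted p = 7.13e-14, counts 2 and 17 adjusted over the list alone). Targets of the oxidative stress factor SKN-1 had 16 negative and 2 positive differences of 27 (median -0.42, camera adjusted p = 3.95e-06, counts 3 and 17 adjusted over the list alone). Its largest difference was in gst-4 (difference in log2 change -1.27, SE 0.09). The DNA replication, proteasome and SKN-1 lists were already higher in starved rsks-1 than in starved N2, as given below. That starved level enters their negative differences. Body wall muscle markers had 15 negative and 2 positive differences of 21 (median -0.36, camera adjusted p = 3.90e-12). Neuropeptide differences were called positive in 70 of 95 cases and negative in 0 (median 0.57, camera adjusted p = 5.79e-31, counts 74 and 1 adjusted over the list alone). Neuron markers had 8 positive and 0 negative differences of 24 (median 0.16, camera adjusted p = 2.93e-05). Ribosome biogenesis genes had 10 positive and 9 negative differences of 53 (median -0.01 but mean 0.05, camera adjusted p = 0.325 with the test upward, with the median turned to 0.10 and adjusted p = 0.0382 under library totals alone, counts 10 and 10 adjusted over the list alone). In all the response differed for 3737 genes, 1515 positive and 2222 negative, and under library totals alone 2351 of 3790 were positive. Camera called 22 of the 41 lists, 15 with an estimated correlation. Of the genes at least 2-fold changed on feeding in N2, 1005 (43.8%) of the higher ones had a negative difference and 669 (25.2%) of the lower ones a positive one, with the opposite sign called for 84 and 129, from a choice of genes with the same limit.

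The raga-1 and rsks-1 responses were compared with each other to set the GTPase mutant against the kinase mutant. The RNA tts-1 went from 1077 ± 51.3 to 216 ± 18.8 CPM in raga-1 and from 2988 ± 186 to 20.6 ± 1.08 CPM in rsks-1 (difference in log2 change 4.85, SE 0.12), with adjusted p = 2.98e-13 (edgeR QL, Benjamini-Hochberg). The apical matrix gene noah-2 differed the other way (difference in log2 change -7.15, SE 0.30), as did idpc-4 and idpp-12 (differences in log2 change -7.65 and -7.62, SE 0.83 and 0.91). The size for idpp-12, with at most 3 counts in starved rsks-1, depends on the prior count. A positive difference was found for fmo-2 (difference in log2 change 4.44, SE 0.29). Ribosome biogenesis genes had 46 negative and 0 positive differences of 53 (median -0.70, camera adjusted p = 1.27e-17). The differences for aminoacyl-tRNA synthetases were negative in 19 of 20 cases (median -0.61, camera adjusted p = 1.37e-11) and for mitochondrial ribosomal proteins in 52 of 66 with 1 positive (median -0.44, camera adjusted p = 9.96e-09, counts 1 and 55 adjusted over the list alone). Molting cycle and apical matrix genes were negative in 31 and positive in 4 of 47 cases (median -1.56, camera adjusted p = 4.05e-07, counts 4 and 32 adjusted over the list alone). Autophagy genes had 19 positive and 1 negative differences of 27 (median 0.76, camera adjusted p = 3.30e-11, counts 20 and 1 adjusted over the list alone). The response differed for 6199 genes, 2645 positive and 3554 negative, the positive share going from 42.7% to 54.2% under library totals alone and to 52.5% with only the libraries compared. Camera called 28 of the 41 lists, 21 with an estimated correlation.

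**Figure D3:**
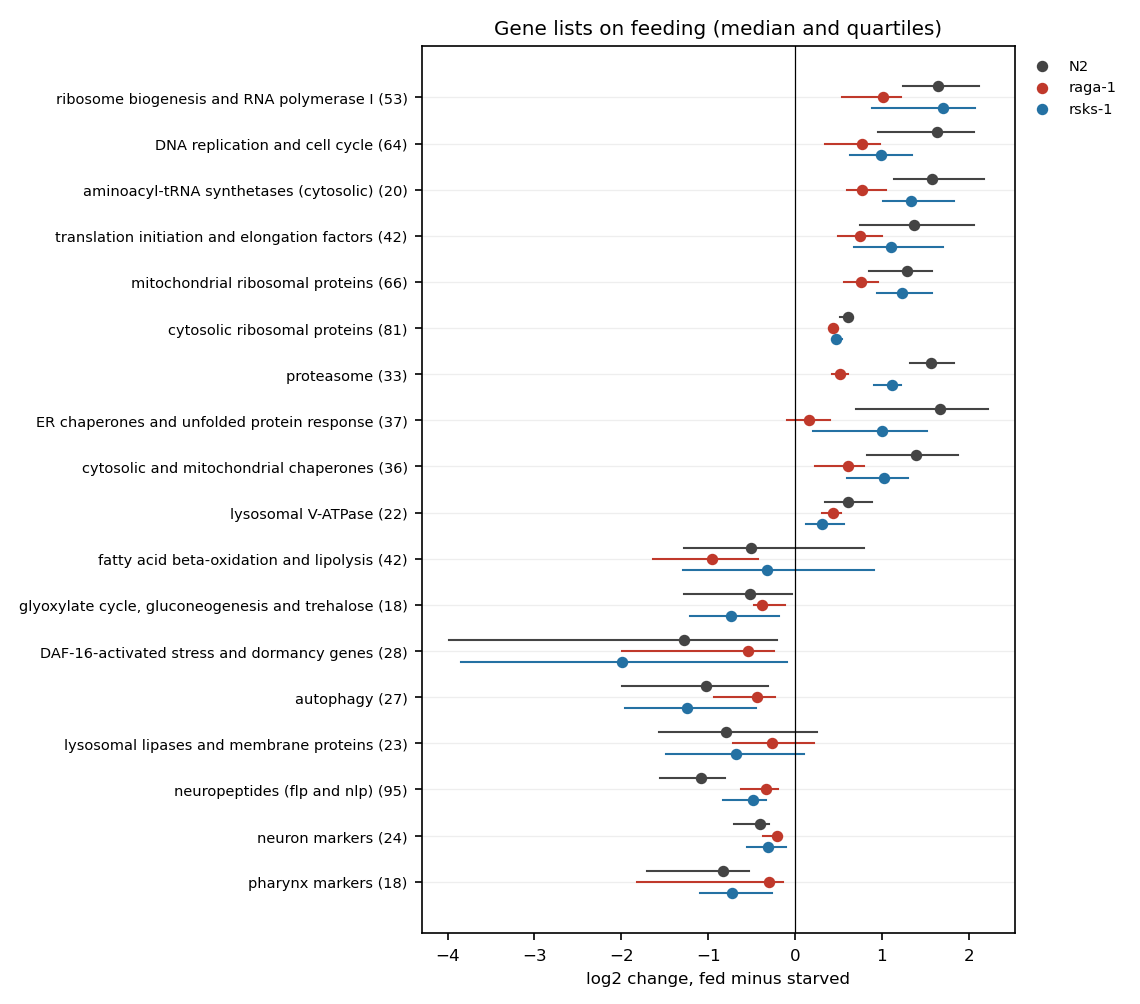
Median (points) and quartiles (lines) of log2 change on feeding for gene lists in N2, raga-1 and rsks-1, with the number of tested genes of each list in parentheses. The median of ER chaperones was 1.67 in N2, 0.16 in raga-1 and 1.00 in rsks-1, and that of autophagy genes -1.03, -0.44 and -1.24.

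Mutants were then compared with N2 in the starved state, before any food. In starved raga-1 larvae cuticle collagen genes were higher than in N2: col-130 was at 45.2 ± 1.53 CPM against 0.386 ± 0.165 CPM and col-146 at 30.1 ± 1.69 against 0.204 ± 0.144 CPM (log2 changes 6.88 and 7.08, SE 0.20 and 0.27). The adjusted p for col-130 was 9.29e-64 (edgeR QL, Benjamini-Hochberg). Of 106 tested collagen genes 77 were higher and 4 lower (median 1.67, camera adjusted p = 8.70e-20, counts 77 and 5 adjusted over the list alone). Many are close paralogues, between which reads may be shared. Molting cycle and apical matrix genes were higher in 24 and lower in 5 of 47 cases (median 0.47, camera adjusted p = 0.00559, counts 25 and 5 adjusted over the list alone). The lectin clec-206 (ratio 206.3, 95% counting interval 70.4 to 1002) and idpp-12 (ratio 161, 95% counting interval 54.7 to 781) were higher from 3 counts each in N2, and idpc-4 was higher (log2 change 7.03, SE 0.33). Lower in starved raga-1 were fmo-2, which was at 43.01 ± 2.38 CPM against 878 ± 7.89 CPM, the lysosomal lipase lipl-5 and asm-3 (log2 changes -4.35, -3.33 and -3.23, SE 0.04, 0.06 and 0.12). ER chaperones were higher in 31 and lower in 2 of 37 cases (median 0.64, camera adjusted p = 1.97e-14). Its highest were hsp-4 and the choline kinase ckb-2 (log2 changes 3.08 and 2.16, SE 0.06 and 0.10). Body wall muscle markers were higher in 18 of 21 cases (median 0.49, camera adjusted p = 2.00e-16, counts 19 and 0 adjusted over the list alone), led by dim-1 and the troponin gene tnt-2 (log2 changes 1.28 and 1.09, SE 0.03 and 0.03). P450, UDP-glucuronosyltransferase and glutathione S-transferase genes were higher in 86 of 178 with 40 lower (median 0.35, camera adjusted p = 0.000513, counts 88 and 41 adjusted over the list alone). The highest of these were cyp-35A4 and cyp-35A5 (log2 changes 6.76 and 6.63, SE 0.13 and 0.19).

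Cytosolic ribosomal protein genes were lower in 80 of 81 cases (median -0.48, camera adjusted p = 3.26e-46), within a narrow range led by rps-13 (log2 change -0.67, SE 0.03). Respiratory chain genes were lower in 34 of 42 (median -0.27, camera adjusted p = 2.01e-11, counts 0 and 35 adjusted over the list alone). Genes of the TCA cycle were lower in 17 of 26 with 4 higher (median -0.16, camera adjusted p = 9.10e-06). Fatty acid synthesis, desaturation and elongation genes were lower in 15 of 28 with 8 higher (median -0.42, camera adjusted p = 9.21e-06, counts 8 and 17 adjusted over the list alone), including the elongase elo-5 (log2 change -2.81, SE 0.05). Lysosomal lipases and membrane proteins were lower in 13 and higher in 2 of 23 cases (median -0.38, camera adjusted p = 6.35e-05). Fatty acid oxidation genes were higher in 27 and lower in 11 of 42 (median 0.33, camera adjusted p = 0.000419), led by ech-9 and the carnitine palmitoyltransferase cpt-4 (log2 changes 4.06 and 3.39, SE 0.12 and 0.15). DNA replication genes were lower in 41 and higher in 3 of 64 (median -0.34, camera adjusted p = 0.000582, counts 4 and 43 adjusted over the list alone). In all 7417 genes differed, 3797 higher and 3620 lower in raga-1, with 1230 and 571 at least 2-fold. Camera called 19 of the 41 lists, 16 with an estimated correlation. The share of calls that were higher was 51.2%, with 48.4% under relative log expression factors and 48.8% with DESeq2, which turn the majority. It was 67.5% under library totals alone, which moved the median of all genes from -0.01 to 0.11.

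In fed larvae, raga-1 mutants had higher levels than N2 of the collagens col-146 (at least 91.1-fold higher, 0 counts in fed N2) and col-96 (log2 change 5.61, SE 0.27). The groundlike gene grl-21 (ratio 148.6, 95% counting interval 50.7 to 722) was higher too, as were the pharyngeal gland gene phat-5 and the cation ATPase catp-3 (log2 changes 5.96 and 5.72, SE 0.23 and 0.12). They had lower levels of nas-3 at 0.429 ± 0.284 against 27.9 ± 0.668 CPM, col-149, pud-3 and sym-1 (log2 changes -6.01, -5.001, -3.99 and -3.61, SE 0.22, 0.17, 0.17 and 0.22). The adjusted p for nas-3 was 2.54e-52 (edgeR QL, Benjamini-Hochberg). Proteasome genes were lower in 32 of 33 cases (median -0.99, camera adjusted p = 1.58e-20), with pas-5 at 62.3 ± 3.27 against 166 ± 4.26 CPM (log2 change -1.42, SE 0.05). DNA replication and cell cycle genes were lower in 59 of 64 with 1 higher (median -1.21, camera adjusted p = 2.15e-19). The lowest were the cyclin cyb-3 and mcm-7 (log2 changes -1.98 and -1.90, SE 0.09 and 0.07). Translation factors were lower in 39 of 42 (median -0.73, camera adjusted p = 4.62e-22) and aminoacyl-tRNA synthetases in all 20 (median -0.88, camera adjusted p = 1.15e-16). So were cytosolic ribosomal proteins in 78 of 81 with 1 higher (median -0.65, camera adjusted p = 1.42e-39, counts 1 and 79 adjusted over the list alone) and mitochondrial ribosomal proteins in 64 of 66 with 1 higher (median -0.64, camera adjusted p = 4.39e-15). In the ribosome biogenesis list 49 of 53 were lower and 2 higher (median -0.56, camera adjusted p = 4.39e-15). Its largest differences were in ebp-2, fib-1, exos-4.1 and ncl-1 (log2 changes -1.37, -0.92, -0.89 and -0.88, SE 0.10, 0.03, 0.06 and 0.04). Of these, ebp-2 is named as a microtubule end-binding protein and ncl-1 is known as a repressor of nucleolar size. ER chaperones, higher in starved raga-1, were lower in 31 and higher in 3 of 37 cases in fed raga-1 (median -0.90, camera adjusted p = 7.27e-16, counts 4 and 31 adjusted over the list alone). Neuropeptide genes were higher in 86 of 95 cases with 1 lower (median 0.87, camera adjusted p = 5.78e-23, counts 87 and 2 adjusted over the list alone) and neuron markers in 22 of 24 (median 0.40, camera adjusted p = 8.36e-10, counts 23 and 0 adjusted over the list alone). Autophagy genes were higher in 16 of 27 with 4 lower (median 0.35, camera adjusted p = 3.64e-05), led by lgg-2 (log2 change 2.15, SE 0.05). In all 8911 genes differed, 4070 higher and 4841 lower, with 1299 and 739 at least 2-fold, and 2282 and 336 under library totals alone. Camera called 22 of the 41 lists, 20 with an estimated correlation. Under library totals alone the share of calls that were higher went from 45.7% to 71.2% and the median of all genes to 0.31.

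In starved rsks-1 larvae the transthyretin-like gene ttr-50 was at 10.8 ± 2.39 CPM against 1.02 ± 0.473 CPM in N2, and pud-3 and pud-4 were higher (log2 changes 3.43, 3.32 and 3.21, SE 0.26, 0.09 and 0.10). The adjusted p for ttr-50 was 9.71e-23 (edgeR QL, Benjamini-Hochberg). Lower were the invertebrate lysozyme ilys-5, the enoyl-CoA hydratase ech-7, the cathepsin B gene cpr-2 and the hydroxyacyl-CoA dehydrogenase hacd-1 (log2 changes -2.48, -2.07, -1.99 and -1.73, SE 0.12, 0.07, 0.12 and 0.05). SKN-1 oxidative stress targets were higher in 21 of 27 cases with 2 lower (median 0.62, camera adjusted p = 9.66e-15, counts 22 and 2 adjusted over the list alone). The highest were the glutathione S-transferases gst-38 and gst-30 (log2 changes 1.75 and 1.45, SE 0.18 and 0.19). DAF-16 genes were higher in 14 and lower in 5 of 28 (median 0.32, camera adjusted p = 2.14e-05, counts 15 and 5 adjusted over the list alone). Its highest were the superoxide dismutase sod-3 and the metallothionein mtl-1 (log2 changes 2.12 and 1.83, SE 0.17 and 0.09). DNA replication and cell cycle genes were higher in 43 of 64 with 1 lower (median 0.52, camera adjusted p = 1.09e-14, counts 47 and 1 adjusted over the list alone). Collagens were higher in 43 of 106 with 2 lower (median 0.58, camera adjusted p = 1.22e-11, counts 44 and 2 adjusted over the list alone), and proteasome genes in 21 of 33 (median 0.21, camera adjusted p = 1.43e-05, counts 23 and 0 adjusted over the list alone). Fatty acid synthesis, desaturation and elongation genes were lower in 16 of 28 with 4 higher (median -0.20, camera adjusted p = 2.55e-09, counts 5 and 16 adjusted over the list alone), led by elo-5 (log2 change -1.57, SE 0.05). Germline markers were lower in 11 of 29 and none was higher (median -0.44, camera adjusted p = 0.000339, counts 0 and 12 adjusted over the list alone), as for the PIWI gene prg-1 (log2 change -1.06, SE 0.12). Cytosolic ribosomal proteins were higher in 20 and lower in 3 of 81 (median -0.01 but mean 0.001, camera adjusted p = 0.568 with the test upward). In all 3792 genes differed, 2120 higher and 1672 lower, with 330 and 142 at least 2-fold. Camera called 21 of the 41 lists, 15 with an estimated correlation. Under library totals alone the share of calls that were higher went from 55.9% to 45.4%.

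In fed rsks-1 larvae pud-1.1, the myo-inositol transporter hmit-1.2 and the P450 gene cyp-13B1 were higher than in N2 (log2 changes 4.78, 3.24 and 2.73, SE 0.57, 0.28 and 0.12). Both pud-1.1 and hmit-1.2 have close paralogues. Lower were spp-4, ilys-5, the aspartyl protease asp-12 and the cathepsin B gene cpr-5, which was at 208 ± 13.4 against 881 ± 10.2 CPM (log2 changes -3.54, -3.11, -2.27 and -2.08, SE 0.22, 0.07, 0.18 and 0.03). The adjusted p for cpr-5 was 2.44e-89 (edgeR QL, Benjamini-Hochberg). Secreted and lysosomal proteases were lower in 16 and higher in 6 of 26 cases (median -0.39, camera adjusted p = 7.84e-06). Neuropeptide genes were higher in 85 of 95 cases and none was lower (median 0.82, camera adjusted p = 1.87e-40, counts 87 and 0 adjusted over the list alone). Neuron markers moved the same way by less, with their values given among the results flagged for a closer look. ER chaperones were called lower in 33 and higher in 0 of 37 (median -0.59, camera adjusted p = 1.06e-33, counts 1 and 34 adjusted over the list alone). The lowest were hsp-4, pdi-2 and the BiP gene hsp-3 (log2 changes -1.29, -1.25 and -1.13, SE 0.07, 0.03 and 0.03). Proteasome genes were lower in 31 of 33 (median -0.28, camera adjusted p = 7.22e-13). In the fatty acid synthesis list the acyltransferase dgat-2 and the desaturases fat-2 and fat-3 were higher (log2 changes 2.00, 1.597 and 1.45, SE 0.08, 0.03 and 0.03). That list had 10 higher and 7 lower of 28 (median 0.03, camera adjusted p = 0.00122). Cytosolic ribosomal proteins were lower in 46 and higher in 3 of 81 (median -0.11, camera adjusted p = 5.96e-09, and adjusted p = 0.293 with an estimated correlation, counts 3 and 51 adjusted over the list alone). Translation factors were lower in 30 and higher in 5 of 42 (median -0.26, camera adjusted p = 7.01e-08, counts 6 and 32 adjusted over the list alone). DNA replication genes, higher in starved rsks-1, had 7 higher and 14 lower of 64 when fed (median -0.06, camera adjusted p = 0.524, counts 7 and 11 adjusted over the list alone). Germline markers were lower in 13 and higher in 2 of 29 (median -0.56, camera adjusted p = 0.0130). In all 5629 genes differed, 2455 higher and 3174 lower, with 568 and 176 at least 2-fold. With only the libraries compared 114 were at least 2-fold lower. Camera called 27 of the 41 lists, 22 with an estimated correlation. Under library totals alone the share of calls that were higher went from 43.6% to 56.9%.

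Some genes differed from N2 in both mutants. In starved larvae 170 genes were at least 2-fold higher in both mutants, against 28.8 for independent lists, and 50 at least 2-fold lower, against 5.8. In fed larvae the counts were 295 against 52.4 and 36 against 9.2. For differences in the feeding response 176 genes had a positive difference of at least 2-fold in both, against 28.1, and 133 a negative one, against 18.4. The same N2 libraries enter both sides of each overlap, so part of the excess may come from them. Data simulated with no mutant effect gave 0 such genes, a value that leaves out the effects and so does not measure what the shared libraries add. Over 9327 genes of at least 10 CPM in a group, the log2 differences of the mutants had r = 0.326 starved, 0.519 fed and 0.456 for the feeding response. The simulated data gave 0.556, 0.589 and 0.585. With no mutant effect the simulated r comes from the shared N2 libraries alone, so it is no yardstick for the observed r. The covariances of the log2 differences were 0.0929, 0.2174 and 0.1990, against 0.0078, 0.0132 and 0.0217 in the simulated data. Spread between the N2 libraries, as far as the replicates measure it, thus gave little of the observed covariance.

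**Figure D4:**
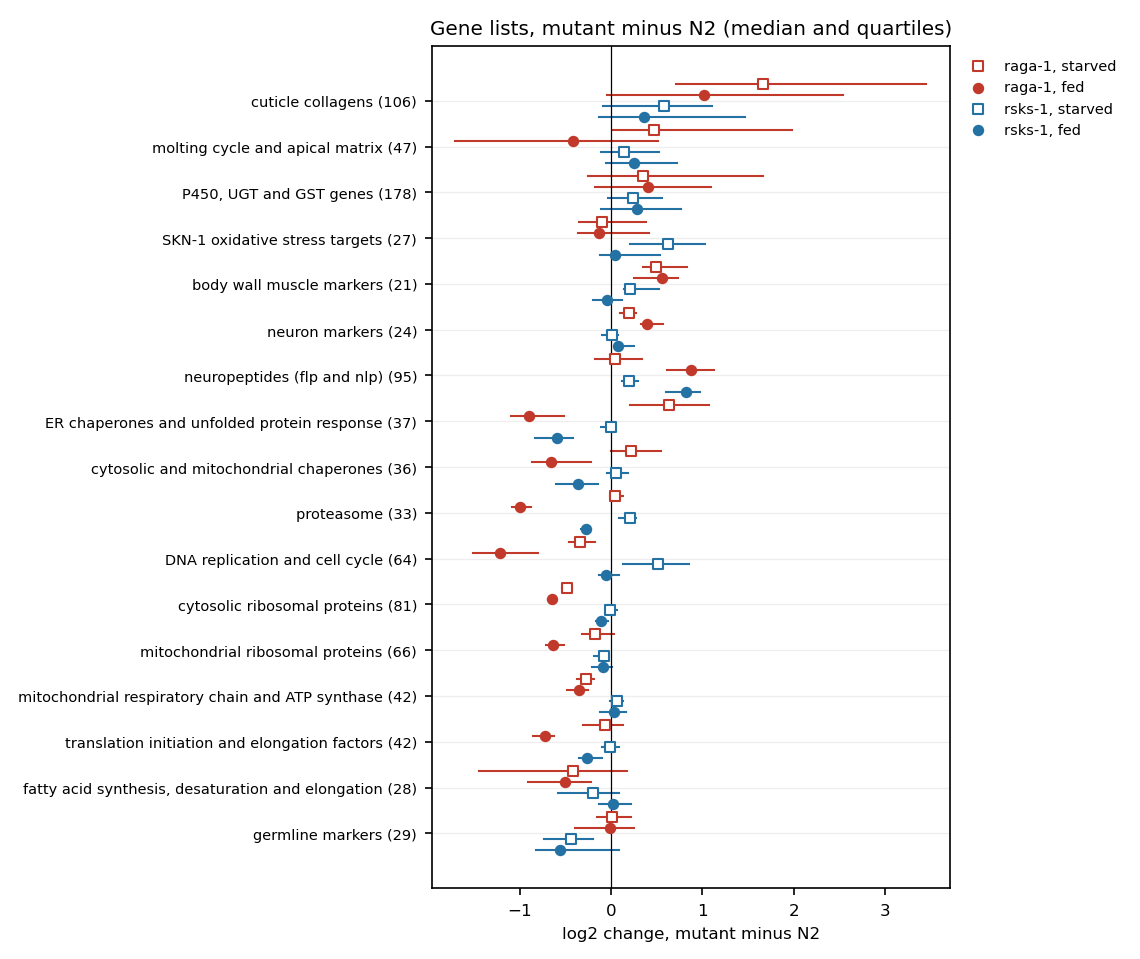
Median (points) and quartiles (lines) of the log2 difference of each mutant from N2 in starved (open squares) and fed larvae (filled circles), with the number of tested genes of each list in parentheses. Collagens lay at 1.67 in starved raga-1, neuropeptides at 0.87 in fed raga-1 and 0.82 in fed rsks-1, and DNA replication at -1.21 in fed raga-1.

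**Figure D5:**
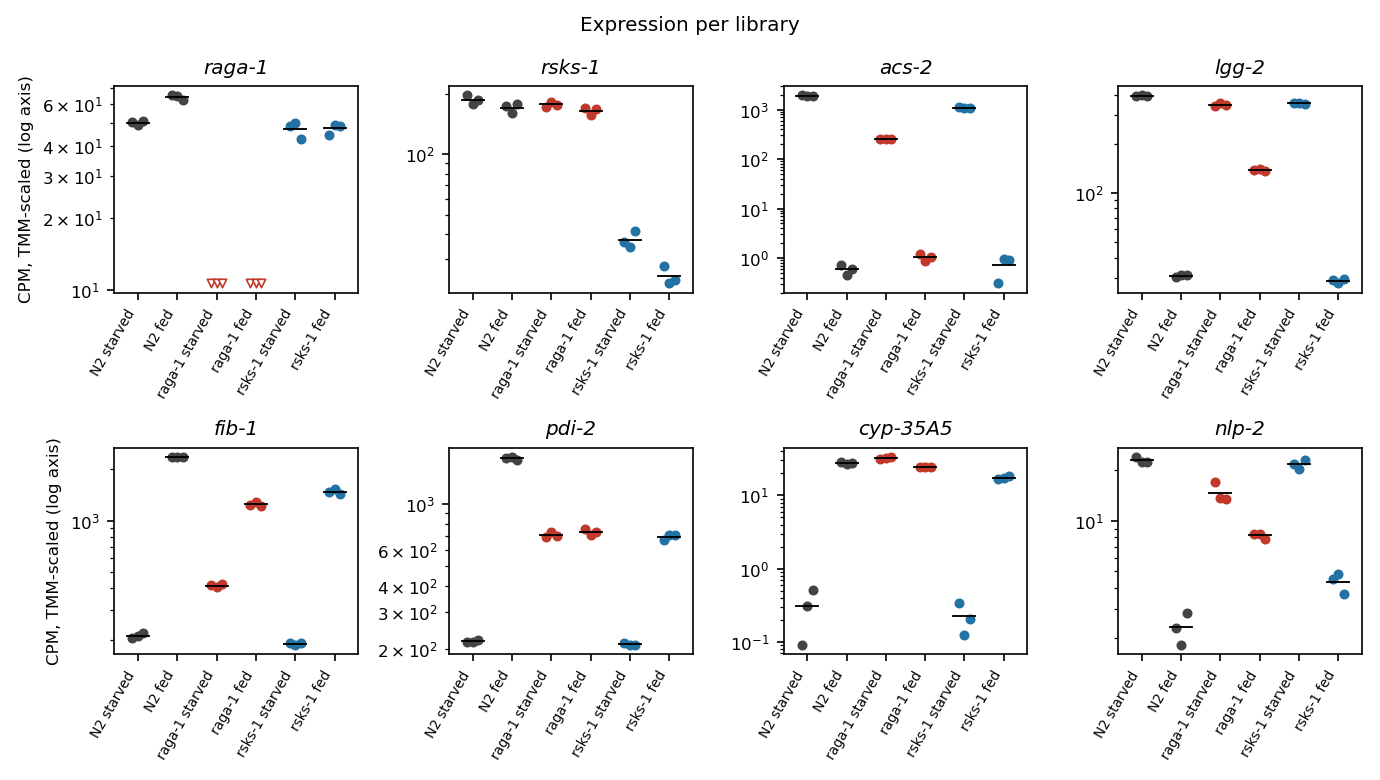
TMM-scaled CPM of 8 genes in each library on a log axis, with the group mean as a bar and libraries with 0 counts as open triangles at an arbitrary position below the lowest value. The 6 raga-1 libraries held 0 counts of raga-1, and pdi-2 was at 1647 CPM in fed N2 and 731 CPM in fed raga-1.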

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

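The genes and lists counted in this paragraph differ between genotypes by a test of the difference between feeding responses, while the collagen and neuropeptide patterns below come from comparisons within a state or genotype. The tests of depth, scaling, larval mixture, stage and neuronal share below were chosen only after the result was seen, and the splits of the libraries were set before the data were examined. Between raga-1 and N2 the response differed for 7110 genes and 23 lists, with differences in log2 change of cyp-35A5 -6.83, sym-1 -6.46, clec-206 -8.21, nas-3 -7.40, hsp-4 -3.17, pdi-2 -2.87, fib-1 -1.89, lgg-2 2.33, amt-1 5.46, cyp-37B1 6.17, mltn-1 5.37. Between rsks-1 and N2 it differed for 3737 genes and 22 lists, with fat-2 2.41, fat-3 2.22, lipl-3 3.18, cyp-37B1 3.85, col-93 -2.92, spp-4 -2.78, gst-24 -2.62, gst-4 -1.27, pdi-2 -1.199, pdi-3 -1.19, rsks-1 -0.49, raga-1 -0.34. Between raga-1 and rsks-1 it differed for 6199 genes and 28 lists, with tts-1 4.85, fmo-2 4.44, idpc-4 -7.65, idpp-12 -7.62, noah-2 -7.15. The sizes for clec-206, nas-3, cyp-37B1, amt-1, mltn-1 and idpp-12 depend on the prior count.

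Genotype labels were exchanged among the fed and among the starved libraries in 100 of 200 possible splits. The real split called 7110 genes for raga-1 against N2 and the highest other 5814, for rsks-1 against N2 3737 and 3153, and for raga-1 against rsks-1 6199 and 4753. Among the splits drawn 1, the real one, was as large in each. Splits that mix genotypes within a group raise its spread, and the median of the other splits was 0. Such splits call few genes by design, so they cannot exclude chance. A full exchange of the genotypes in fed libraries, not among those drawn, called 9415, 5710 and 8889 genes, more than the real splits. That exchange turns the difference of 2 genotype effects into their sum, so it reflects the genotypes' own effects in the 2 states. For each feeding and genotype comparison the 10 splits of 6 libraries are too few for a share under 0.05; the real counts were 10399, 8775 and 9968 for feeding in N2, raga-1 and rsks-1, 7417 and 8911 for starved and fed raga-1 and 3792 and 5629 for starved and fed rsks-1, and the highest other was 0 in each.

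The first pattern is the smaller feeding response in raga-1, with a slope of 0.420. Not every list followed it: fatty acid oxidation genes had medians of -0.51 on feeding in N2 and -0.95 in raga-1. With every library thinned to the lowest total the slope was 0.432, which argues against depth as its cause. With library totals alone it was 0.428. A shift of all raga-1 log2 changes by up to 1 moves the slope only between 0.355 and 0.486, so the setting itself could not test scaling. Genes at least 2-fold higher on feeding in N2 had medians of 1.54 in N2 and 0.68 in raga-1. Those at least 2-fold lower had -1.83 and -0.81. Scaling moves all changes the same way, so the smaller size in both directions argues against it as the whole cause, for genes chosen on N2 libraries. A share of larvae that did not respond at all would need to be 67.8% for the rising genes, yet of 1522 genes of at least 100 CPM in starved raga-1, 55 kept under 33.9% of their level after feeding, 0.5 of that share, among them acs-2, icl-1 and adh-1. A mixture of fully responding and unresponsive larvae is argued against by this, while a weaker or later response in each animal remains a hypothesis. A starved level that already differed from N2 also enters the response. Of 2224 genes at least 2-fold lower on feeding in rsks-1, 826 were lower and 493 higher in starved raga-1 than in starved N2. Of 1823 at least 2-fold higher, 782 were higher and 269 lower, so a changed starved level is left open too.

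The second pattern is the higher level of collagen genes in starved raga-1, with a list median of 1.67. With library totals alone the median was 1.79. That setting also moved the median of all genes from -0.01 to 0.11, so it could only raise the list and did not test scaling. Scaling moves all genes alike, so it cannot lift this list relative to the median of all genes. Older, growing larvae could bring collagen transcripts with them; the DNA replication list had a median of -0.34 with quartiles of -0.47 and -0.18, too close to 0 to exclude a small share. Late embryos could do so too; 2 of 12 embryonic genes were higher, with a list median of 0.04, and these explanations cannot be told apart from an effect of the mutation because the counts are few and every starved raga-1 library shares the genotype.

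The third pattern is that neuropeptide genes fell on feeding in N2 and were higher in both fed mutants than in fed N2. Their median on feeding in N2 was -1.09 against -0.40 for neuron markers, a difference of -0.68 (95% bootstrap interval -0.85 to -0.46, 10000 draws of genes). The draws treat genes as independent, while the estimated correlation within the neuropeptide list was 0.153. The interval is therefore likely too narrow, and it leaves out the spread between libraries. It argues only weakly against a lower share of neuronal RNA as the whole cause of the fall in N2. Of 24 neuron markers 22 were also higher and 0 lower in fed raga-1 (median 0.40, camera adjusted p = 8.36e-10, counts 23 and 0 adjusted over the list alone), and 10 higher and 0 lower in fed rsks-1 (median 0.08, camera adjusted p = 0.000193), so the share of neuronal RNA could add to the difference there. The lowest median in a fed mutant minus fed N2 over the scalings tried was 0.80. Library totals raised the medians, from 0.871 to 1.193 in raga-1 and from 0.824 to 0.889 in rsks-1, so these settings tested scaling only weakly. Scaling moves all genes alike, and their medians were 0.007 in fed raga-1 and -0.004 in fed rsks-1. It cannot lift this list relative to them. A change in neuropeptide expression within neurons that follows feeding and depends on both genes may be an explanation, as a hypothesis found and tested on the same data. The genes were listed by flp and nlp names, so a change outside neurons is not excluded.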

How the results depend on the processing

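Library totals alone, thinning to the lowest total and lists without each library were chosen after seeing the data; the other alternatives were set before the data were examined. Of 3128 alternative values for 214 log2 changes of named genes, 3117 kept direction and side of the threshold, 11 kept direction but no longer passed it, and 0 reversed. Those no longer passing were mltn-1 for raga-1 against N2 responses without fed raga-1 replicate 1, pud-1.1 and col-153 for rsks-1 against N2 responses (DESeq2, and without fed N2 replicate 1, col-153 also without replicate 3), pud-1.1 in starved raga-1 (DESeq2), and the target genes as given in the report. With fewer libraries the test has less power; for the others the cause was not tested.

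The numbers of genes called stayed within 1.5 times their value under every alternative. Without each library in turn they were 10033 to 10183 for feeding in N2, 8262 to 8414 for raga-1 and 6770 to 7035 for starved raga-1 against N2. Under library totals alone the genes at least 2-fold higher and lower in fed raga-1 were 2282 and 336, since that scaling shifts all genes. With only the libraries compared, 114 genes were at least 2-fold lower in fed rsks-1; the cause was not tested. The fry test called 40 lists for feeding in N2, 37 for raga-1 against N2 responses, 35 for starved and 36 for fed raga-1, as it does not compare a list with other genes. With the replicate number as a block 10362 genes were called for feeding in N2; the residuals of same-numbered libraries had a mean correlation of -0.001 over 45 pairs, so the numbers do not pair samples.

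The response size of raga-1 (0.420) was 0.413 with genes selected in N2, 0.428 with library totals alone, 0.432 with thinned libraries, and 0.397 to 0.426 without each library in turn. That of rsks-1 (0.782) was 0.761 with genes selected in N2, 0.799 with thinned libraries, and 0.718 to 0.793 without each library in turn, lowest for both without fed N2 replicate 1; the cause was not tested.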

Other observations

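The test of the starvation genes below was chosen only after the result was seen. Body wall muscle markers in fed raga-1 had 18 higher and 1 lower of 21 (median 0.56, camera adjusted p = 1.32e-13, counts 18 and 2 adjusted over the list alone). In starved rsks-1 they had 16 higher and 2 lower of 21 (median 0.21, camera adjusted p = 4.36e-16, counts 17 and 2 adjusted over the list alone) and on feeding in rsks-1 5 higher and 15 lower of 21 (median -0.37, camera adjusted p = 0.000546). Pharynx markers on feeding in N2 had 2 higher and 15 lower of 18 (median -0.83, camera adjusted p = 0.000232). In raga-1 they had 1 higher and 14 lower of 18 (median -0.30, camera adjusted p = 0.000143) and in starved rsks-1 against N2 1 higher and 12 lower of 18 (median -0.24, camera adjusted p = 7.08e-06, counts 2 and 13 adjusted over the list alone). Intestine markers had, for the difference between rsks-1 and N2 responses, 1 higher and 11 lower of 19 (median -0.19, camera adjusted p = 2.12e-06, counts 1 and 12 adjusted over the list alone). They had between raga-1 and N2 responses 3 higher and 12 lower of 19 (median -0.28, camera adjusted p = 0.00175). Hypodermis and seam markers in fed rsks-1 had 6 higher and 0 lower of 14 (median 0.24, camera adjusted p = 0.00908, counts 7 and 0 adjusted over the list alone).

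Histone genes, many of them close paralogues between which reads are shared, had on feeding in raga-1 2 higher and 13 lower of 21 (median -0.86, camera adjusted p = 0.000880). Intracellular pathogen response genes had on feeding in rsks-1 3 higher and 16 lower of 23 (median -1.21, camera adjusted p = 0.00890) and in N2 3 higher and 15 lower of 23 (median -0.93, camera adjusted p = 0.0345, and adjusted p = 0.0753 under library totals alone). Insulin-like peptide genes had in fed rsks-1 against N2 11 higher and 0 lower of 21 (median 0.46, camera adjusted p = 0.000522, and adjusted p = 0.0528 with an estimated correlation). Lists not past the threshold on feeding in N2 were C-type lectins with 32 higher and 50 lower of 109 (median -0.45, camera adjusted p = 0.247) and lysozymes and saposin-like proteins with 11 higher and 17 lower of 35 (median -0.54, camera adjusted p = 0.189, counts 12 and 17 adjusted over the list alone). So were nutrient transporters with 26 higher and 20 lower of 57 (median 0.16, camera adjusted p = 0.700) and glycolysis with 12 higher and 8 lower of 22 (median 0.17 but mean -0.08, camera adjusted p = 0.657). The same held for sperm genes with 2 higher and 4 lower of 13 (median -0.74, camera adjusted p = 0.457) and embryonic genes with 4 higher and 3 lower of 12 (median -0.18, camera adjusted p = 0.892).

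A hypothesis is that starved raga-1 larvae may carry a weaker starvation programme than starved N2. Over 2224 genes at least 2-fold lower on feeding in rsks-1, the median of raga-1 minus N2 in starved larvae was -0.16 (quartiles -0.65 and 0.33), and -0.04 with library totals alone. Of them 826 were lower and 493 higher. Over 1823 genes at least 2-fold higher on feeding in rsks-1 the median was 0.16, and 0.28 with library totals alone, with 782 higher and 269 lower. The genes went both ways, so the test leaves the hypothesis open. Of 571 genes at least 2-fold lower in starved raga-1 than in starved N2, 385 were at least 2-fold lower on feeding in N2, against 107.8 for independent lists, and 25 higher. Of 1230 at least 2-fold higher, 326 were at least 2-fold higher on feeding in N2, against 200.5, and 297 lower. Starved N2 libraries enter both sides of these overlaps, which favours the same sign, and how much this adds was not measured.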
